A study of Mus musculus with 8 samples.

How the data were processed

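Facial skin of 8 C57BL/6 mice at postnatal day 28 was profiled by CAGE, a method that sequences the capped 5′ ends of RNA and so maps transcription start sites. Per the labels, 4 samples were lesional skin of Cre-positive mice with floxed Ikk2 (the gene Ikbkb, which encodes a kinase that activates NF-κB) and 4 were non-lesional skin of control mice. The Cre line is written Nestin-cre in the series text and Nectin-cre in the sample labels. Lesion and genotype change together in this design. Total RNA was isolated on spin columns and checked for integrity, and libraries were made from it with a commercial CAGE kit, per the labels' protocols.

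The deposited table holds 1 row per CAGE tag cluster and gene, with the cluster's chromosome, start, end and strand, the gene symbol that the authors gave it or a dot, and 8 columns of values. The submitters' processing notes name the aligners BWA and HISAT2 and the genome build mm9, with no version. How tags were joined into clusters, the smallest number of tags that made a cluster, whether libraries were pooled for this step and the rule that tied a cluster to a gene are not given in the sources used here. Neither is it stated whether starts are counted from 0 or from 1, so coordinates are printed as deposited and the span of a cluster is its end minus its start.

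The names of the 8 value columns match no title, description or other label of a sample. Column order, and the values themselves, were not taken as evidence of which column belongs to which mouse. These 8 columns were therefore not used in any result, no difference between lesional and non-lesional skin was computed, and the depth of each library was not analysed here. The planned tests of the 2 groups (a linear or count model of all genes, tests of gene lists between groups, alternative promoter use and the similarity of libraries) were not run. What follows rests on the cluster positions and gene symbols, which describe the catalogue made from the series as a whole. It is not known from this catalogue which group a cluster came from.

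Rows with the same position were counted as 1 cluster, and each of the genes given to it was kept. Gene symbols were matched to the RefSeq gene table of assembly GRCm38.p6, for names and gene types only. Of 16094 symbols in the catalogue, 13829 were current symbols, 1551 were older symbols of a single gene, and 714 were not matched. Among the symbols were 19 that a spreadsheet had turned into dates, and these stayed unmatched. To check the build, the clusters of 12515 protein-coding genes were compared with the 5′ end of the same gene in GRCm38. A cluster lay within 1000 bp of it for 666 genes (5.32%), so the deposited coordinates are not on GRCm38, and no coordinate from that assembly was used.

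There were 32 gene lists, covering pathways, skin compartments and cell types, fixed before the data were examined. For each list, the share of its protein-coding members with at least 1 cluster was compared with the share among all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 32 lists and a threshold of 0.05. Genes are not independent replicates, and this test describes the catalogue rather than mice. A list member entered its share only if its name matched a protein-coding gene of the RefSeq table. Names that led to 1 gene counted once. Krt85, Il36rn, Lacrt and Ahsp were unmatched, so they were not looked up. Cxcl11, Mx1, Mx2, Tpsab1 and Sprr2g were left out as transcribed pseudogenes, and all of these but Cxcl11 had a cluster. The comparison set was all other protein-coding genes, whether or not they are active in skin. A list chosen from genes active in skin, or in most cells, was therefore likely to pass. Passing does not single out a pathway or cell type. Shares carry 95% Wilson intervals, which cover counting error only. For the number of clusters per gene, the median of a list was placed among 10000 random lists of as many protein-coding genes with a cluster. These random lists were not matched on expression, because the value columns were not used. Neighbouring clusters on opposite strands no more than 400 bp apart were called divergent (minus strand first along the chromosome) or convergent (plus strand first). Overlapping neighbours were left out.

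The rule fixed in advance for the genes named in the text always names Ikbkb and Nes. Its other parts rest on adjusted p-values between the groups and could not be applied. Other genes are named as members of the fixed lists or for their number of clusters, and were chosen after the catalogue was seen. All tests on the catalogue, their settings and their alternatives were likewise chosen after the table was seen. On simulated data, 500 divergent pairs placed among 38099 clusters at random positions were recovered at 100.0%. Their spacing was fixed inside the 400 bp limit, so this checks the counting only. Of random lists of 20 protein-coding genes, 3.7% had an unadjusted p under 0.05 (Fisher's exact test). Genes were drawn singly there, whereas the fixed lists hold families of neighbouring genes. The analysis used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.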

Results

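CAGE libraries were made from facial skin of 8 mice at postnatal day 28. Per the labels, 4 were Cre-positive mice with floxed Ikk2 and lesional skin, and 4 were controls with non-lesional skin. The design asks how the set and strength of transcription start sites differ between lesional and control skin. That comparison is not reported, because the columns of values could not be tied to mice by any label. The catalogue of clusters described here was shared by the whole series. A gene with a cluster is a gene whose symbol had been given to at least 1 cluster. This states neither the group that the cluster came from nor, where several genes share it, which of them was transcribed.

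The catalogue held 84475 distinct CAGE tag clusters, 41559 on the plus strand and 42916 on the minus strand. A gene symbol had been given to 46376 of them (54.9%), and these carried 16094 different symbols, counted here as genes. Most of the symbols named protein-coding genes, at 13889 (86.3%). As some genes appeared under both an older and a current symbol, these were 13869 distinct protein-coding genes. A further 604 symbols named long non-coding RNA genes (3.75%) and 625 named pseudogenes (3.88%). The remaining 38099 clusters (45.1%) carried no symbol. More than 1 gene had been given to 940 clusters, with up to 8 genes for 1 cluster, so a cluster shared by neighbouring or overlapping genes does not show which of them was transcribed.

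Clusters with a gene were wider than those without. Their median span was 11 bp with quartiles of 3 and 85 bp, against a median of 3 bp with quartiles of 2 and 11 bp for clusters without a gene. Spans under 10 bp made up 48.3% of clusters with a gene and 73.0% of clusters without a gene. The smallest span was 2 bp in both sets and the largest was 349 bp. That largest cluster belonged to Birc3, an inhibitor of apoptosis induced by NF-κB.

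**Figure D1:**
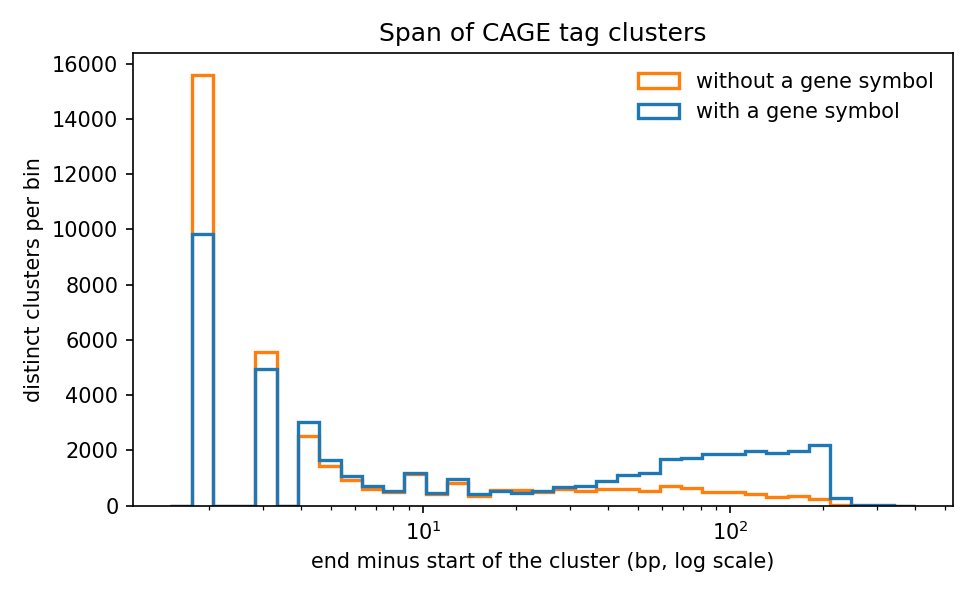
Histogram of the span of each distinct cluster (end minus start in bp, log scale) against the number of clusters per bin, drawn separately for the 46376 clusters with a gene symbol and the 38099 without. Both sets peak at a span of 2 bp, and the clusters with a gene form a further broad group of wide clusters that leads to their higher upper quartile of 85 bp.

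The targeted gene, Ikbkb, had 3 clusters on the minus strand of chromosome 8 (mm9). The widest ran from 23816986 to 23817067, a span of 81 bp. A cluster of 2 bp lay at 23816584 to 23816586 and a cluster of 3 bp at 23780259 to 23780262. CAGE reads the 5′ end of a transcript, and a floxed exon downstream of the start site can be lost without removing that end, so these clusters do not test the deletion. Nes, which encodes the intermediate filament nestin, after which the series text names the Cre line, had 1 cluster on the plus strand of chromosome 3, from 87774995 to 87775119. All 18 members of the NF-κB list had a cluster (100%, 95% Wilson interval 82.4 to 100; 63.3% of other protein-coding genes; adjusted exact p = 0.00107, Fisher's exact test). Among them Nfkb1 had 14 clusters, Rela had 6 and Nfkbiz had 6, while Nfkbia, the gene of the inhibitor IκBα, had 2.

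Genes of the epidermis and its appendages were covered almost completely. All 36 protein-coding members of the cornified layer list had a cluster (adjusted exact p = 1.32e-06, Fisher's exact test). So did all 39 tested members of the hair shaft and inner root sheath list (adjusted exact p = 8.28e-07, Fisher's exact test). Krt85, also on that list of 40, was unmatched and not looked up. All 17 of the hair follicle stem cell list had a cluster (adjusted exact p = 0.00168, Fisher's exact test). The barrier lipid list had 21 of 22 members (adjusted exact p = 0.0028) and the sebaceous list had 20 of 22 (adjusted exact p = 0.0105). Flg, the gene of the barrier protein filaggrin, had 8 clusters and its neighbour Flg2 had 7. Krt1 had 14 clusters and Krt10 had 13, whereas Lor, the gene of loricrin, had 1 cluster of 10 bp. Of the stress and hyperproliferation genes of keratinocytes, 32 of 35 had a cluster (adjusted exact p = 0.00107), including Krt6a with 9, Krt16 with 10 and Sprr1b with 16. With clusters of at least 10 bp this call ended, at 26 of 35 (adjusted exact p = 0.137). All 25 cell cycle genes had a cluster (adjusted exact p = 0.000243), with 4 for Mki67 and 4 for Top2a. The Sprr2, Lce1 and Lce3 families, and the keratin and Krtap genes of these lists, hold related copies. How alike the copies are was not examined, and their cluster counts are uncertain because reads can be shared between copies.

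All 20 fibroblast and collagen genes had a cluster (adjusted exact p = 0.000925, Fisher's exact test), with 24 clusters for Col1a1 and 23 for Col1a2. The matrix protease and wound matrix list had 21 of 22 (adjusted exact p = 0.0028), and the endothelial list had 17 of 18 (adjusted exact p = 0.0091). Each of the 11 melanocyte genes had a cluster (adjusted exact p = 0.0145), with 11 for Dct and 8 for Tyrp1, both enzymes of pigment synthesis. The same held for all 14 Schwann cell and nerve genes (adjusted exact p = 0.00637). Counting only clusters of at least 10 bp ended the calls for matrix genes at 18 of 22 (adjusted exact p = 0.0901), endothelium at 13 of 18 (adjusted exact p = 0.439) and Schwann cells at 12 of 14 (adjusted exact p = 0.101). Of the skeletal muscle genes, 22 of 24 had a cluster (adjusted exact p = 0.00511, Fisher's exact test), including Ttn with 35, Myh1 with 15 and Myh4 with 13. Skeletal muscle lies under facial skin, and whether it was the source of these clusters was not tested. Adipocyte genes, at 12 of 13, did not pass the threshold (adjusted exact p = 0.0581). Nor did cartilage and bone genes, at 5 of 12 (adjusted exact p = 0.185). Salivary and lacrimal gland genes were listed less often than other genes, at 2 of 15 (13.3%, 95% Wilson interval 3.74 to 37.9; adjusted exact p = 0.000632). The 2 were Amy1, with 1 cluster of 120 bp, and Aqp5, with 1 cluster of 11 bp.

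Type 2 cytokine genes and their targets were partly represented. Of 27 members, 21 had a cluster (77.8%, 95% Wilson interval 59.2 to 89.4), which did not differ past the threshold from the 63.3% of other genes (adjusted exact p = 0.198, Fisher's exact test). With clusters of at least 10 bp the direction turned, to 15 of 27 (55.6%) against 59.9% of other genes (adjusted exact p = 0.768). Ccl11, the gene of the eosinophil attractant eotaxin, had a cluster of 156 bp on the plus strand of chromosome 11 from 81871274 to 81871430, and Ccl8 had one of 91 bp from 81928607 to 81928698 on the same strand. Ccl24 had a cluster of 57 bp and Il33, an epithelial alarm cytokine, had 2 clusters of which the wider spanned 77 bp. Several cytokine genes had a single narrow cluster, of 4 bp for Il4, 3 bp for Il5, 2 bp for Tslp and 2 bp for Ccl17. Narrow clusters were not particular to cytokines, as the widest cluster was also 4 bp for the keratin gene Krt2 and for Tchh. What the span of a cluster reflects was not tested. Il13, Il31, Il9, Il25, Ccl22 and Ccr4 had no cluster under those symbols among those analysed here. The itch list had 18 of 23 members (adjusted exact p = 0.222), among them Osmr with 6 clusters and Il31ra with a single cluster of 6 bp.

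Chemokine ligands were listed for 32 of 36 genes (adjusted exact p = 0.00223, Fisher's exact test) and interferon-stimulated genes for 21 of 23 (adjusted exact p = 0.00725). The list of IL-1, IL-17, IL-20 and IL-36 family and antimicrobial genes had 19 of 26 (adjusted exact p = 0.459). It held clusters for Il36g (6), S100a9 (10) and Il1b (3), and none for Il17a, Il17f or Il22 in the clusters analysed here. Counting only clusters of at least 10 bp ended the calls for chemokines at 19 of 36 (52.8%, then below the 59.9% of other genes; adjusted exact p = 0.49) and interferon-stimulated genes at 18 of 23 (adjusted exact p = 0.137). The IL-1, IL-17, IL-20 and IL-36 list then stood at 15 of 26 (57.7%), also below other genes (adjusted exact p = 0.899).

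Among immune cell types, markers of monocytes and macrophages were complete, with 20 of 20 (adjusted exact p = 0.000925, Fisher's exact test), a call that ended with clusters of at least 10 bp at 15 of 20 (adjusted exact p = 0.352). Mast cell genes were listed for 11 of 13 (adjusted exact p = 0.194), with the proteases Cpa3 and Cma1 at clusters of 208 and 140 bp. Dendritic and Langerhans cell genes were listed for 13 of 16 (adjusted exact p = 0.222), including Cd207, the gene of langerin. Neutrophil genes were listed for 12 of 16 (adjusted exact p = 0.47), and for 8 of 16 with clusters of at least 10 bp (then below other genes; adjusted exact p = 0.535). Ly6g, Ngp, Mpo and Elane had no cluster. Asprv1, Il1b, Mmp8 and Hdc had a cluster and also stand on other fixed lists, so the count is not specific to neutrophils. Of 18 T cell genes, 11 had a cluster (adjusted exact p = 0.838), among them Cd3e with a span of 197 bp and Foxp3, the regulatory T cell factor, with a span of 4 bp. Basophil and eosinophil genes stood at 5 of 14 (35.7%; adjusted exact p = 0.0673). With clusters of at least 10 bp alone, they stood at 1 of 14 (adjusted exact p = 0.000485) and cartilage and bone genes at 2 of 12 (adjusted exact p = 0.0107), both then below other genes. No B cell or plasma cell gene of the 10 on that list had a cluster (0.0%, 95% Wilson interval 0.0 to 27.8; adjusted exact p = 0.000351). Red blood cell genes were listed for 5 of 8 (adjusted exact p = 1). Those without a cluster were Hba-a2, Hbb-bs and Hbb-bt, whereas Hbb-b1 and Hbb-b2 were listed. Whether this count was set by the globin symbols in use or by reads shared between globin copies was not tested. Because the value columns were not used, a missing cluster cannot be told from a low level of expression or from the unstated rule for calling clusters.

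**Figure D2:**
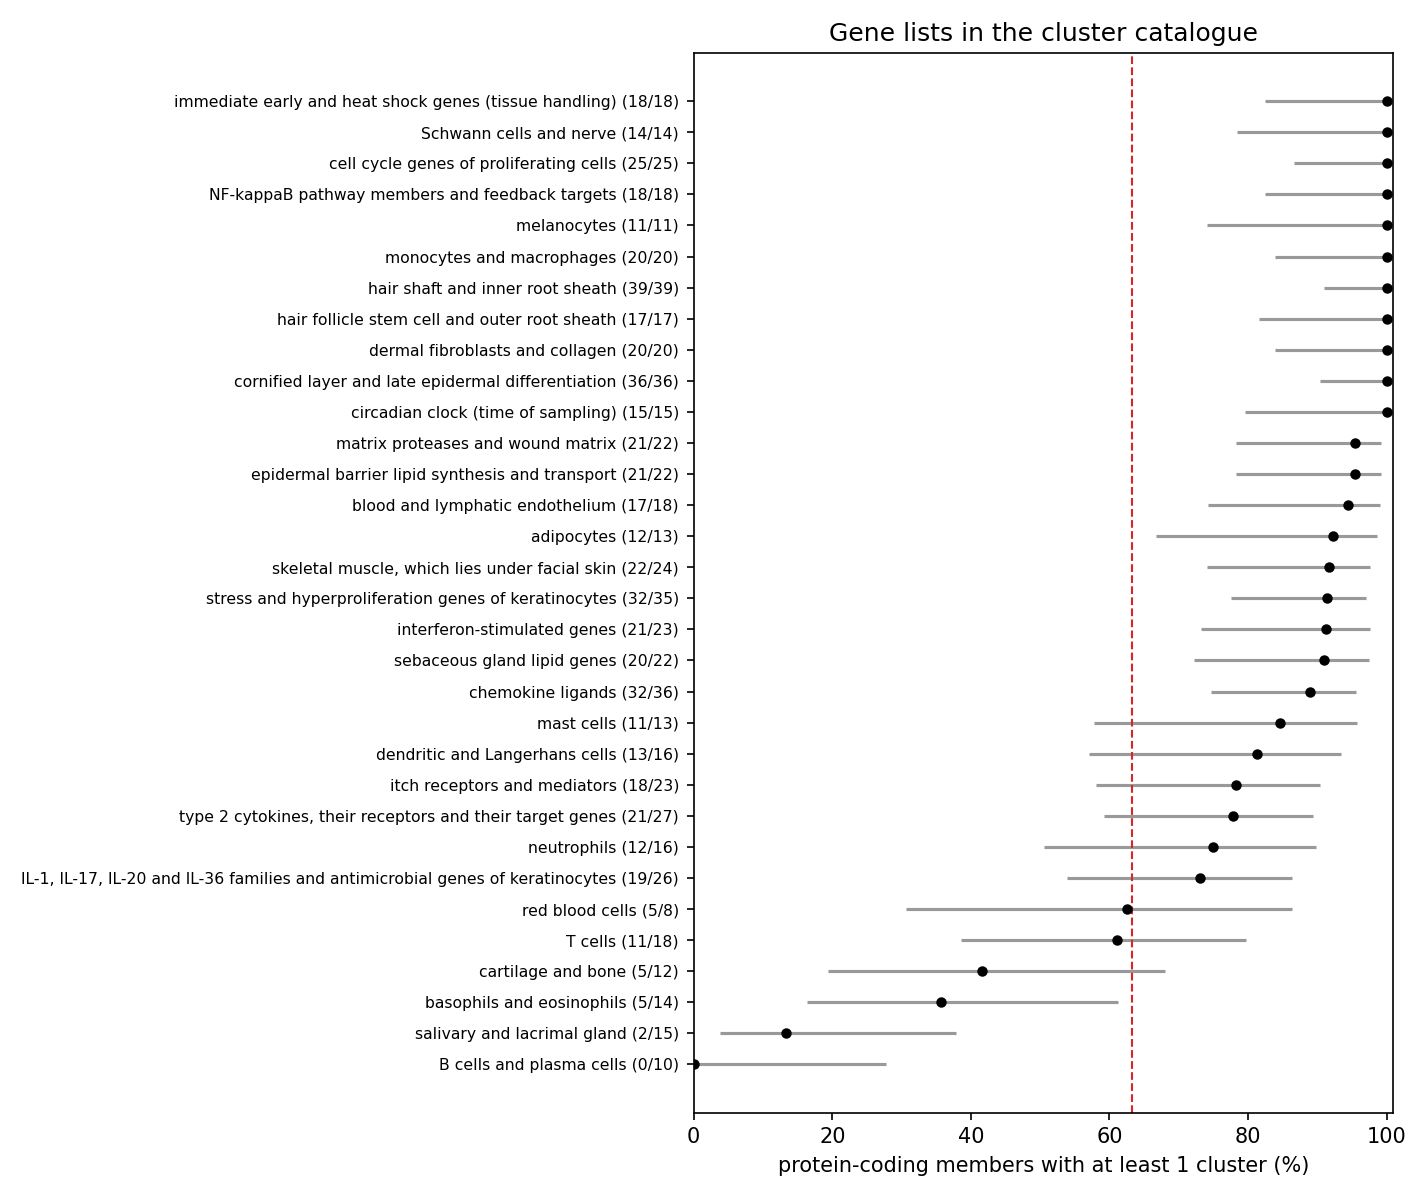
Share of the protein-coding members of each of the 32 fixed gene lists that had at least 1 cluster (points, percent), with 95% Wilson intervals (grey lines) and the numbers in brackets; the dashed line marks 63.3%, the share of all 21900 protein-coding genes. At 100% lie 11 lists, among them the cornified layer, hair shaft, fibroblast and macrophage lists. The NF-κB, cell cycle, immediate early and heat shock, and clock lists are also among these. The gland list (2 of 15) and the B cell list (0 of 10) lie lowest.

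Over the 32 lists, 19 were above other genes, 2 were below and 11 did not pass the threshold. With clusters of at least 10 bp, 12 were above and 4 below. The 2 lists meant to show tissue handling and time of sampling were among the 19: all 18 immediate early and heat shock genes (adjusted exact p = 0.00107, Fisher's exact test) and all 15 clock genes (adjusted exact p = 0.00391) had a cluster. Passing was therefore not particular to lists of skin genes.

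A single cluster was found for 7352 genes (45.7%) and 2 or more for 8742 (54.3%), and 815 genes had 10 or more. With clusters of at least 10 bp, 2 or more were found for 5424 of 14678 genes (37.0%). Of the gaps between neighbouring clusters of 1 gene, 57.6% were at most 100 bp, with a median of 65 bp, and whether neighbouring clusters are separate start sites was not tested. Malat1, a nuclear non-coding RNA, had the most, at 74, followed by Hnrnpu at 40 and Hsp90ab1 at 36. The basal keratin gene Krt14 had 28 and Wnt5a had 30. Among the lists, hair shaft genes had a median of 6 clusters per listed gene, above every one of 10000 random lists (percentile 100). That list holds many related keratin and Krtap genes, so its cluster counts carry the uncertainty of shared reads given above. Hair follicle stem cell genes had a median of 5 (percentile 99.9), fibroblast genes 4 (percentile 99.5), muscle genes 4 (percentile 99.7) and sebaceous genes 4 (percentile 99.3), against a median of 2 for protein-coding genes with a cluster. The cornified layer list, at a median of 3, lay at percentile 97.2. A median of 1, the lowest that a listed gene allows, was found for 17 of the 32 lists. These medians depended on narrow clusters. With clusters of at least 10 bp, they were 2 for hair shaft (percentile 95.8), hair follicle stem cell (91.2), fibroblast (94.4) and sebaceous genes (92.0), 1.5 for muscle genes (85.7) and 1 for cornified layer genes (45.0), against a median of 1 for protein-coding genes.

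Clusters far apart within 1 gene were less frequent, and whether they are separate start sites was not tested. Counting clusters of at least 10 bp, 1417 of 14678 genes (9.65%, 95% Wilson interval 9.19 to 10.1) had neighbouring clusters on the same strand separated by at least 1000 bp. With clusters of any span, 2493 of 16094 genes (15.5%) did.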

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

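All alternatives given here were chosen after seeing the data, because the planned ones (other normalizations, tools, filters on low values, pseudocounts, sets of libraries left out in turn, and other gene set tests) need the columns of values and were not run. No paired analysis was possible because the value columns could not be tied to samples, so the replicate numbers of the labels belong to no column. Lesional and control skin also came from different mice. The replicate numbers are only those of the sample titles and are not known to mark pairs. Counting only clusters of at least 10 bp raised the share of clusters with a gene from 54.9% to 70.0%, lowered the genes with 2 or more clusters from 8742 to 5424, lowered the lists above other genes from 19 to 12 and raised those below from 2 to 4. Under that setting, chemokine genes went from 25.6 percentage points above other genes to below them (a difference of -7.13, not past the threshold), as many of their clusters span under 10 bp. As the meaning of span was not tested, a call that ended with this cut is not shown to be false. Of the other 31 lists, 23 kept their side of the threshold, 6 lost the call and 2 gained one. Of those 23, 19 also kept their direction, and 4 that passed the threshold in neither setting did not: the type 2 list went from 14.5 percentage points above other genes to a difference of -4.35, the IL-1, IL-17, IL-20 and IL-36 list from 9.76 to -2.21, the neutrophil list from 11.7 to -9.91 and the red blood cell list from -0.83 to 2.60. Counting rows in place of distinct clusters gave 55.5% with a gene. Genes with clusters far apart rose from 1417 to 2493 with clusters of any span and to 2078 with a separation of 500 bp. The divergent share of opposite-strand pairs without a gene was 63.7% at 400 bp, 58.7% at 1000 bp, 64.2% at 200 bp and 67.3% for clusters of at least 10 bp. With current symbols alone, genes listed only under an older symbol counted as having no cluster. Then 20 lists were above and 2 below, and the adipocyte list passed the threshold (adjusted p = 0.0146, Fisher's exact test). Its count was 12 of 13 in both settings, while the share of other genes fell from 63.3% to 57.1%. Without passing the threshold in either setting, the T cell list then turned from -2.22 to 3.95 percentage points. The red blood cell list turned from -0.83 to 5.34. Both turns came from the lower share of other genes, as the counts stayed at 11 of 18 and 5 of 8. The depth of the libraries, and what it limits, was not analysed here.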

Other observations

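Each test in this part was chosen after the table had been seen. Predictions were written before the results for the divergent share of pairs without a gene and for the divergent pairs' distance to named clusters. The same was done for the gaps between neighbouring clusters in genes with many clusters. Other comparisons in this part, including the convergent pairs' distance and the random placement of clusters within genes, had no prediction written in advance. The catalogue held clusters of genes from both sex chromosomes. Xist, the non-coding RNA of the inactive X chromosome, had 27 clusters, and the Y-linked genes had 3 (Uty), 2 (Ddx3y), 1 (Eif2s3y) and 1 (Kdm5d). The labels used here do not give the sex of the mice.

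Clusters without a gene lay on opposite strands in a preferred order. Of such neighbour pairs within 400 bp, 351 were divergent and 200 convergent, a divergent share of 63.7% (95% Wilson interval 59.6 to 67.6), where strands placed at random would give equal numbers. The share was 67.6% where both clusters had a gene, from 1337 divergent and 642 convergent pairs. Where 1 of the 2 clusters had a gene, 2011 pairs were divergent and 1095 convergent (64.7%, 95% Wilson interval 63.0 to 66.4). The order was therefore not particular to the unnamed pairs. A candidate explanation for the unnamed pairs is transcription in both directions from a shared element, such as an enhancer. The order of strands is what this would give. Pairs with a gene had the same order, so it does not single out an enhancer. Another is that they are start sites of known genes left without a symbol: 48.4% of the divergent pairs lay within 5000 bp of a cluster with a gene and 51.6% lay farther away (95% Wilson interval 46.4 to 56.7). Of the 200 convergent pairs, 51.5% lay farther away (44.6 to 58.3), so the divergent pairs were not seen to lie closer to named clusters than the convergent ones. Neither part was clearly the larger. The share expected at random positions was not computed, so these shares cannot decide on this explanation, and it stays open.

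Genes with 10 or more clusters may owe their number in part to 1 promoter region being divided into adjoining clusters. Of 10337 gaps between neighbouring clusters of these genes, 68.8% (95% Wilson interval 67.9 to 69.7) were at most 100 bp, with a median of 36 bp. Short gaps were also common over all genes, at 57.6% of 31398 gaps, and genes chosen for many clusters tend to short gaps. With the same clusters placed at random between the outermost clusters of each gene, a check added after the result was seen, the share was 40.2% on average and at most 40.8% in 100 draws. Clusters that gather in exons or at several nearby start sites would also give such an excess, so splitting is not singled out by it. High expression of hair, collagen and muscle genes, which would bring more tags along the transcript, was not tested because the values were not used. No biological explanation for the number of clusters was tested.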
